A study of Homo sapiens with 16 samples.

How the data were processed

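Ribosome footprints on XBP1 were measured by ribosome profiling in HEK293 cells, an established line derived from human embryonic kidney. XBP1 encodes the transcription factor of the IRE1 branch of the unfolded protein response. Per the labels' protocols, lysates were footprinted with RNase I, ribosomes were pelleted, the protected fragments were extracted, and libraries were made by linker ligation, reverse transcription, circularization, rRNA depletion and PCR. No molecular identifiers are named there, so counting intervals and detection floors cover counting error only.

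The deposited values are 1 table per library for 1850 positions of the unspliced XBP1 transcript, each position being that of a read's 5' end. Per the file headers, the first value column is a raw read count per position. Per the file headers, the second is RPM, the count scaled to the total reads of the library, and the headers do not say whether total reads are sequenced, mapped or rRNA-free reads. HISAT2 2.0.3 and the build hg38 are named in the submitters' processing notes, without settings. Trimming, length selection, treatment of reads that map to several places and removal of duplicates are not given in the sources used here. Dividing the deposited counts by the deposited RPM gave 1 constant per library within 0.083%, and that constant was taken as the library total.

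Libraries were grouped by the labels into 8 groups of 2: control, Hsp70L1, Pelo or both siRNAs, each with DMSO or thapsigargin for 4 h. The labels number the replicates but do not say that they were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Chi-square tests of the counts over 30-nt bins separated the 2 libraries of every group, so none was counted as a duplicate of another. Totals ran from 10888616 to 28332380 reads per library. Reads on XBP1 numbered 392 to 1370 in the DMSO libraries and 4739 to 15221 in the thapsigargin libraries. A floor of 3 reads corresponded to 0.106 to 0.276 RPM.

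No transcript sequence was used, so coding features were placed from the data with the known lengths of the proteins, 261 residues for XBP1u and 376 for XBP1s, and with cleavage by IRE1 in codon 165. The start codon was put at position 77, 12 nt after the initiation peak of 5' ends at position 65. This placed the 26-nt intron at 570 to 595, the XBP1u stop codon at 860 to 862 and the XBP1s stop codon at 1231 to 1233. The last peak of 5' ends lay at 1216, 15 nt before the XBP1s stop codon. The arrest peptide window covered codons 236 to 261 with a margin of 15 nt before them, positions 767 to 862. Regions were defined by the 5' end of the read. A footprint whose 5' end lies shortly before the intron also covers it. How reads across the splice junction were placed on the unspliced transcript is not given in the sources used here, so region limits near the cleavage sites are approximate.

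From the counts, 4 quantities were computed per library: the XBP1 level (summed RPM, tested as log2), the share of coding reads past the XBP1u stop codon, the share of reads from the start codon to the XBP1u stop codon that lay in the arrest peptide window, and the share of coding reads in the intron. RPM is relative to all reads of a library and so depends on what else was sequenced, whereas the shares within XBP1 do not. Each factor was tested with a two-sided exact stratified permutation test over all 16 libraries, with labels permuted within the 4 combinations of the other factors (1296 relabellings, smallest p 0.0015). Differences are means over those combinations, with 95% intervals from the spread pooled over the 8 groups (8 residual degrees of freedom). Adjusted p-values are Benjamini-Hochberg values over the 15 planned tests. A contrast of 2 against 2 libraries cannot give an exact p below 0.33. Along the transcript, 30-nt bins counted from the start codon, with a mean share of at least 0.1%, were tested with edgeR's quasi-likelihood test, the XBP1 total serving as library size, and Benjamini-Hochberg adjustment over bins at 0.05. Bin shares are relative to all XBP1 reads, so a higher share in one part lowers the others. Up to 5 bins per comparison are named: those with the largest change past the threshold and the same direction in all 4 strata. These tests, the definitions of the regions and the rules were fixed before the data were examined, while the positions of the region limits were then placed from the data.

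The replicate number was also used as a block, with labels flipped within the 8 pairs of same-numbered libraries (256 relabellings, smallest p 0.0078). Whether the numbers pair the libraries was checked from the replicate differences of log2 bin shares, correlated across bins between groups. Over the 40 bins past the filter, all 28 pairs of groups had correlations above 0.1 (0.106 to 0.821). Over the 39 bins of the coding region without the filter, 24 of 28 did (0.027 to 0.772). With both sets, the 4 pairs that differ only in thapsigargin and the 4 that differ only in Hsp70L1 siRNA were all above 0.1. For Pelo siRNA, 4 of 4 pairs passed with the filter and 3 of 4 without it, so the pairing for that factor is unsettled. The labels do not state a shared day or culture.

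Alternatives included leaving out each library, the block, a linear model, other windows, denominators, scales and bin widths, no filter, TMM, and DESeq2. For a recalculated level or share, only its own p-value was replaced before adjustment, and the other p-values stayed those of the main analysis. Reads by reading frame, frame shares corrected per library, positions shifted to the P site and bins before the intron alone were added after the data had been seen. The bin test was tested on simulated counts for the Hsp70L1 siRNA comparison (40 bins, 8 of them changed). It called 27.5% of bins changed 1.5-fold, 85.6% of those changed 2-fold and 100% of those changed 3-fold. These counts were drawn with the same spread for all bins and no offset between replicate numbers, so the rates may not hold for the real libraries. The permutation test of the level, simulated for the same comparison with the observed spread of 0.29 on the log2 scale, gave an unadjusted p under 0.05 in 7% of simulations with no change, 42% at a log2 change of 0.25 and 89% at 0.5. That spread includes the offset between replicate numbers, so these rates too may not hold for the real libraries. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The mRNA levels of XBP1, HSPA14 and PELO were not analysed here, so neither knockdown efficiency nor footprints per mRNA is given.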

Results

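Ribosome footprints along XBP1 were counted in 16 libraries of HEK293 cells in a crossed design. XBP1 lies on chromosome 22 at 28794560 to 28800569 (GRCh38, gene ID 7494). Cells carried control siRNA, siRNA against Hsp70L1, siRNA against Pelo, or both, and received DMSO or thapsigargin for 4 h, with 2 libraries per group. Hsp70L1 (gene HSPA14) is the Hsp70 chaperone of the mammalian ribosome-associated complex. Pelo is a ribosome rescue factor that acts on stalled ribosomes. Thapsigargin blocks the calcium pump of the endoplasmic reticulum and causes ER stress, under which IRE1 removes a 26-nt intron from XBP1 mRNA. The unspliced mRNA encodes XBP1u, whose C-terminal end arrests its own translation. The spliced mRNA is read in another frame past the intron and encodes the longer transcription factor XBP1s. The series asks what part the ribosome-associated complex plays in this branch of the unfolded protein response.

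The libraries held 10888616 to 28332380 reads each. XBP1 had 392 to 1370 reads in the DMSO libraries and 4739 to 15221 in the thapsigargin libraries, so values in DMSO are the less precise. Nearly all footprint 5' ends lay between the initiation peak at position 65 of the transcript and the XBP1s stop codon at 1231, with a last peak at 1216. Before the initiation peak lay 0% to 0.255% of the XBP1 reads of a library. Of all 75856 XBP1 reads, 59 (0.078%) lay past that codon. The second Hsp70L1 siRNA library in DMSO spread its reads over fewer positions than the others. When thinned to 392 reads, it covered 155 positions, against 195 to 244 in the other DMSO libraries.

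**Figure D1:**
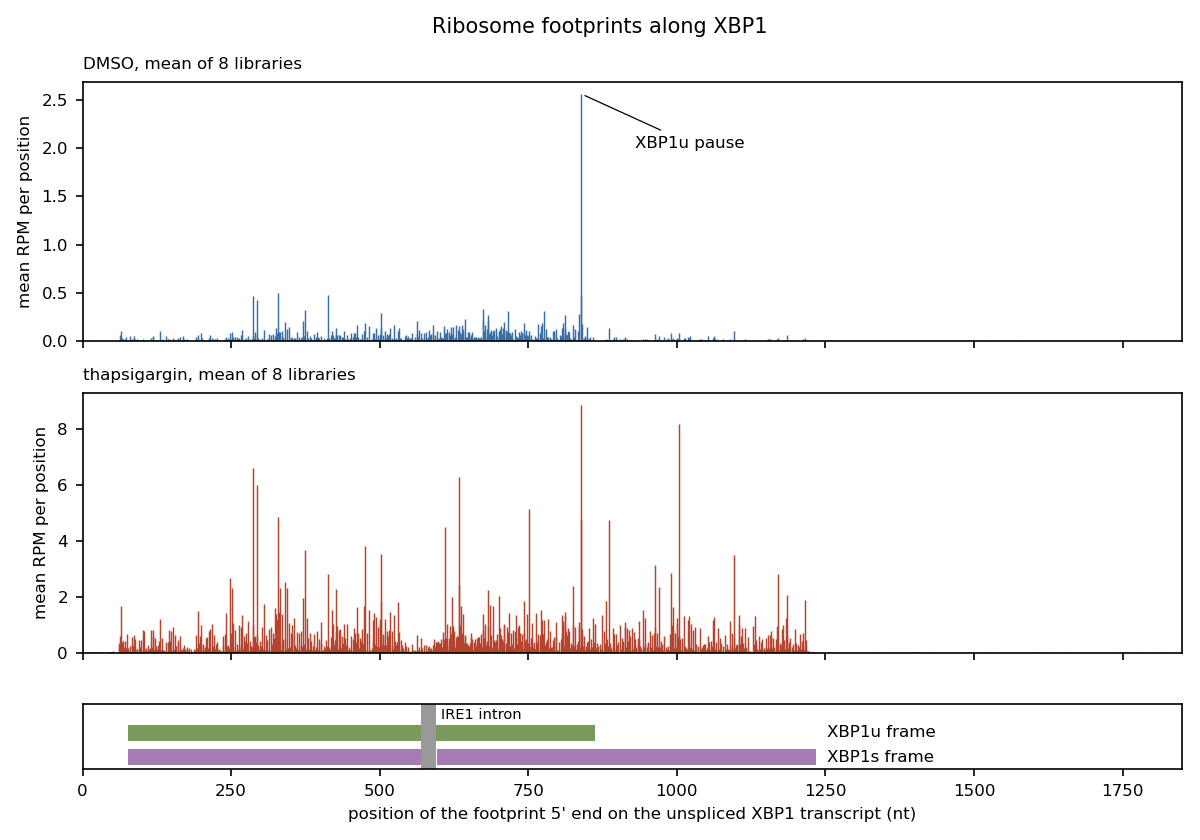
Mean RPM of footprint 5' ends (y axis) at each position of the unspliced XBP1 transcript in nt (x axis), for 8 DMSO libraries (top) and 8 thapsigargin libraries (middle, on a larger scale), with the reading frames and the intron below. In DMSO a single peak at position 839 stands above the rest at 2.56 RPM, and few reads lie past the XBP1u stop codon, where the thapsigargin profile continues.

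The first comparison asked how ER stress changed ribosome occupancy of XBP1. Thapsigargin raised the XBP1 footprint level from 38.4 ± 6.8 RPM (SD, n = 8) to 507 ± 96 RPM (SD, n = 8). The increase was 13.2-fold (95% interval 10.5 to 16.6) and was seen in 8 of 8 pairs of libraries, with p = 0.0015 in the exact permutation test, the smallest it can give, and an adjusted p of 0.0058. By siRNA it was 13.5-fold with control, 14.3-fold with Hsp70L1, 12.2-fold with Pelo and 12.7-fold with both siRNAs. Because RPM is relative to all reads of a library, a change in total translation or in rRNA content would enter this value. The shares below are free of that.

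Thapsigargin moved ribosomes past the XBP1u stop codon, into the part of the mRNA that only the XBP1s frame reads. This part held 7.19% ± 2.50 of coding reads in DMSO (SD, n = 8) and 27.1% ± 2.1 in thapsigargin (SD, n = 8). The difference was 19.9 percentage points (95% interval 17.4 to 22.5), higher in 8 of 8 pairs (exact permutation p = 0.0015, adjusted p = 0.0058). In RPM, the mean over this part was 2.86 in DMSO and 136 in thapsigargin, a ratio of 47.7 that ranged from 41 to 71.5 over the siRNA conditions. For the coding part before the intron, shared by both proteins, the ratio was 13.3, with a range of 12.1 to 15.1.

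Footprints in the intron went the other way relative to the rest. They made up 2.82% ± 0.62 of coding reads in DMSO (SD, n = 8) and 0.765% ± 0.135 in thapsigargin (SD, n = 8). The share fell by 2.06 percentage points (95% interval −2.69 to −1.43) and was lower in 8 of 8 pairs (exact permutation p = 0.0015, adjusted p = 0.0058). In absolute terms the mean intron level was 1.05 RPM in DMSO and 3.72 RPM in thapsigargin, 3.53-fold, well below the 13.3-fold of the coding part before it. The rise was uneven along the intron. Pooled reads went from 2 to 63 at position 592 and from 1 to 51 at 595, both near its 3' end. At 583 they went from 17 to 33 and at 590 from 23 to 37. How reads across the splice junction were placed is not given, so the intron values in thapsigargin are approximate.

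The arrest peptide window, positions 767 to 862, held 22.3% ± 3.1 of reads up to the XBP1u stop codon in DMSO (SD, n = 8) and 15.8% ± 1.3 in thapsigargin (SD, n = 8). This share fell by 6.53 percentage points (95% interval −9.79 to −3.28), lower in 8 of 8 pairs (exact permutation p = 0.0015, adjusted p = 0.0058). Ribosomes of both frames cross the window. Counting only XBP1u-frame reads past the intron, a measure added after the data had been seen, left a difference of −0.25 points (exact permutation p = 0.97, adjusted p = 0.97). The highest single position in the mean of all 16 libraries was 839, which puts codon 260 of XBP1u in the A site, near the end of the arrest peptide. It held 6.67% ± 1.93 of XBP1 reads in DMSO (SD, n = 8) and 1.77% ± 0.59 in thapsigargin (SD, n = 8). Its level was 2.56 ± 0.83 RPM in DMSO and 8.86 ± 2.7 RPM in thapsigargin (SD, n = 8 each).

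Along the transcript, 23 of 40 bins of 30 nt changed their share of XBP1 footprints with thapsigargin in edgeR's quasi-likelihood test. Of 13 bins that reach or follow the XBP1u stop codon, 11 rose and none fell. Of 10 bins from the one over the 5' cleavage site up to that codon, 8 fell and none rose. Of the 17 bins that end before the intron, 3 rose and 1 fell. The largest increases were at 1097 to 1126 (log2 change 3.33 ± 0.41, SE), from 0.167% to 1.68% of XBP1 reads, and at 917 to 946 (3.18 ± 0.41), from 0.228% to 2.14%. A DMSO library held only 0 to 3 reads in the first of these bins and 0 to 7 in the second, so their rank is uncertain. The bin at 1157 to 1186 rose by 2.52 ± 0.28 on the same scale and that at 1187 to 1216 by 2.30 ± 0.42. The largest decrease was in the bin over the 5' cleavage site, 557 to 586, with a log2 change of −2.29 ± 0.24, from 3.35% to 0.713%. Adjusted p-values of these 5 bins were between 3.3e-07 and 0.00011 in edgeR. Footprints that start in the bin 557 to 586, or in the falling bin before it, 527 to 556, can cross the splice junction. How such reads were placed is not given, so both decreases may partly reflect read placement. The count depends on bin width: 36 of 78 bins of 15 nt and 13 of 21 bins of 60 nt changed. With shares taken within the coding part before the intron alone, 3 of 16 bins changed.

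**Figure D2:**
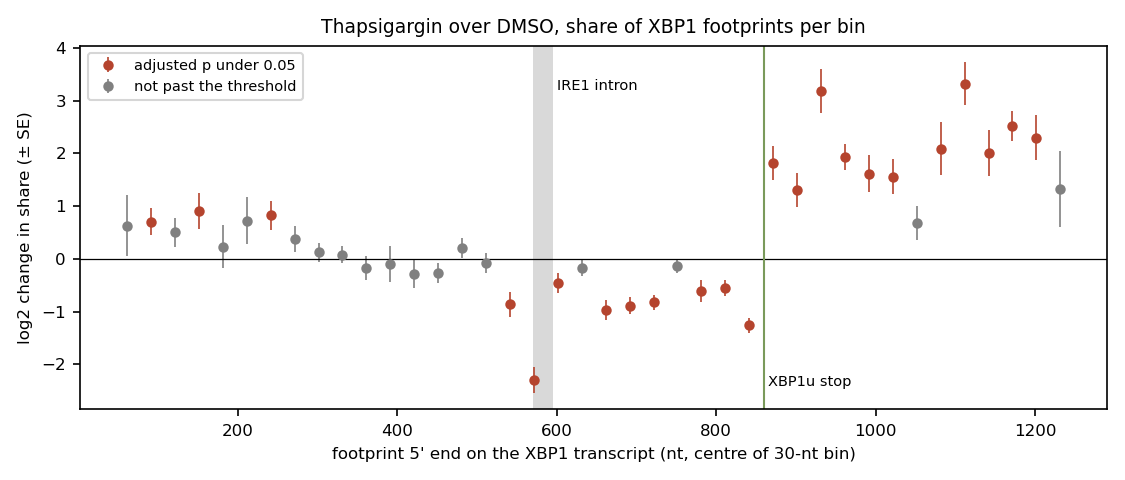
Log2 change in the share of XBP1 footprints, thapsigargin over DMSO (y axis, points with SE from edgeR), for 40 bins of 30 nt placed by their centre on the transcript in nt (x axis), with red marking adjusted p under 0.05. The red points past the XBP1u stop line lie above 0, those from the intron to that line lie below 0, and the lowest point, −2.29, lies at the 5' edge of the intron.

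The second comparison asked whether loss of Hsp70L1 changed translation of XBP1. The XBP1 level was lower with Hsp70L1 siRNA in 8 of 8 pairs of same-numbered libraries, at 0.87-fold (95% interval 0.69 to 1.10). In thapsigargin it was 477 ± 86 RPM with Hsp70L1 siRNA and 536 ± 109 RPM without (SD, n = 4 each). In DMSO it was 35.4 ± 6.8 and 41.5 ± 6.2 RPM (SD, n = 4 each). This did not pass the planned test (exact permutation p = 0.14, adjusted p = 0.35), in which the offset between replicate numbers counts as spread. With replicate number as a block it did (exact permutation p = 0.0078, adjusted p = 0.023).

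The share of coding reads past the XBP1u stop codon was 25.7% ± 1.9 with Hsp70L1 siRNA and 28.5% ± 1.4 without it in thapsigargin (SD, n = 4 each). In DMSO it was 5.98% ± 2.02 and 8.40% ± 2.56 (SD, n = 4 each). Over both treatments the difference was −2.57 percentage points (95% interval −5.13 to −0.0080), lower in 7 of 8 pairs. It missed the threshold after correction (exact permutation p = 0.028, adjusted p = 0.083). It passed with the replicate block (exact permutation adjusted p = 0.047), without the first control siRNA library in DMSO (−3.34, adjusted p = 0.032), and without the second library of both siRNAs in DMSO (−3.13, adjusted p = 0.019). It stayed short of the threshold in 14 of 16 recalculations that left out 1 library, and in 7 of 8 other settings.

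The shares of the arrest peptide window and of the intron did not pass the test with Hsp70L1 siRNA. The arrest peptide window differed by 1.43 percentage points (95% interval −1.83 to 4.68), higher in 6 of 8 pairs (exact permutation p = 0.29, adjusted p = 0.54). Leaving out 1 library at a time gave 0.22 to 2.64, with the lowest adjusted p at 0.065, and counting only XBP1u-frame reads turned the sign (−0.51). The intron share differed by 0.17 points (95% interval −0.46 to 0.80), higher in 5 of 8 pairs (exact permutation p = 0.55, adjusted p = 0.83). Without the second Hsp70L1 siRNA library in DMSO the intron difference was −0.050. None of 40 bins changed in edgeR's quasi-likelihood test, with 3 at an unadjusted p under 0.05, and 0 changed in DESeq2, with 4 unadjusted.

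Whether the effect of Hsp70L1 siRNA depended on ER stress was examined as the difference of its effects in thapsigargin and in DMSO. Hsp70L1 labels were permuted within strata, so the null of this test is no Hsp70L1 siRNA effect in any stratum, not equal effects. The difference was 0.070 on the log2 scale for the level (95% interval −0.59 to 0.73; exact permutation p = 0.80). It was −0.30 percentage points for the share past the XBP1u stop codon (95% interval −5.42 to 4.82; exact permutation p = 0.92). For the arrest peptide window it was 0.32 points (95% interval −6.20 to 6.83; exact permutation p = 0.92). All 3 adjusted p-values were 0.92. The sign turned when 1 library was left out in 7 of 16 cases for the level, 4 of 16 for the share past the stop codon and 3 of 16 for the arrest window. For the share past the stop codon it also turned as log2 density (0.28) and on the logit scale (0.22), and for the arrest window without its margin (−1.75) and around its peak (−1.89). The signs are thus not settled, and the wide intervals leave room for differences as large as the effects themselves.

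The third comparison asked the same of Pelo. The XBP1 level was 1.11-fold with Pelo siRNA (95% interval 0.88 to 1.40), higher in 7 of 8 pairs, which did not pass the test (exact permutation p = 0.26, adjusted p = 0.54). In thapsigargin it was 519 ± 102 RPM with Pelo siRNA and 494 ± 104 RPM without (SD, n = 4 each), and in DMSO 41.4 ± 6.5 and 35.4 ± 6.5 RPM (SD, n = 4 each). With replicate number as a block, the level missed the threshold after adjustment (exact permutation p = 0.023, adjusted p = 0.069), and the pairing for Pelo siRNA is unsettled. The share past the XBP1u stop codon differed by 0.50 percentage points (95% interval −2.06 to 3.06; exact permutation p = 0.63, adjusted p = 0.83). For the arrest peptide window the difference was −0.62 points (95% interval −3.88 to 2.63; exact permutation p = 0.66, adjusted p = 0.83). For the intron it was −0.18 points (95% interval −0.82 to 0.45; exact permutation p = 0.43, adjusted p = 0.72). In edgeR's quasi-likelihood test 0 of 40 bins changed and 0 had an unadjusted p under 0.05, and DESeq2 gave 0 and 0. The sign of these share differences turned when 1 DMSO library was left out. The share past the stop codon gave −0.27 without the first control siRNA library and −0.061 without the second library of both siRNAs. The arrest window gave 0.59 without the first Hsp70L1 siRNA library and 0.060 without the first Pelo siRNA library, and the intron 0.032 without the second Hsp70L1 siRNA library.

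Both siRNAs together were compared with each single siRNA. In thapsigargin the XBP1 level was 504 ± 105 RPM with both, 450 ± 90 RPM with Hsp70L1 siRNA and 534 ± 140 RPM with Pelo siRNA (SD, n = 2 each). The share past the XBP1u stop codon was 25.1% ± 2.6 with both, 26.3% ± 1.5 with Hsp70L1 siRNA and 29.6% ± 0.2 with Pelo siRNA (SD, n = 2 each). Both siRNAs against Pelo siRNA alone gave a difference of −4.49 percentage points (95% interval −9.61 to 0.64), and the libraries of these 2 groups did not overlap. With 2 libraries against 2, the exact permutation test cannot give a p below 0.33, so none of these contrasts could reach the threshold in that test, and their 95% intervals from the spread of all 8 groups included 0. Whether the effect of Hsp70L1 siRNA differed with and without Pelo siRNA was tested over all 16 libraries, a test added later. The difference of effects was 0.19 on the log2 scale for the level (exact permutation p = 0.49) and −0.84 points for the share past the XBP1u stop codon (exact permutation p = 0.76), both with an adjusted p of 0.96.

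**Figure D3:**
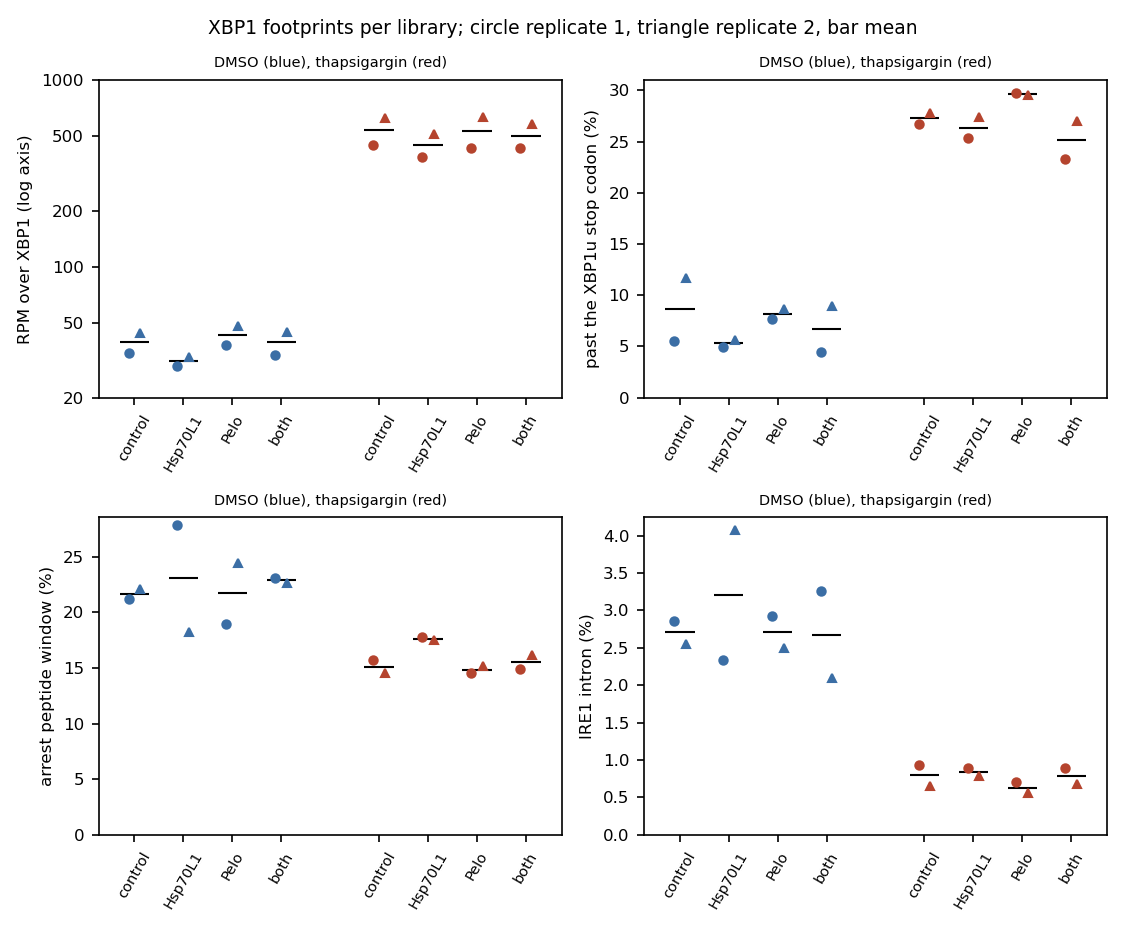
Values per library for the 8 groups, with DMSO in blue, thapsigargin in red, circles for replicate 1, triangles for replicate 2 and bars for the mean of 2 libraries, in 4 panels: XBP1 level in RPM on a log axis, and the percentages of reads past the XBP1u stop codon, in the arrest peptide window and in the intron. The DMSO and thapsigargin libraries do not overlap in any panel, and the triangle lies above the circle in all 8 groups of the level panel.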

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

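Of 411 recalculations of the planned results and bin counts under another setting, 377 kept the result and 8 changed the call. The remaining 26 reversed the direction of a result that was past no threshold either way. For tests, kept means the same direction and side of the threshold. For bin counts it means a number near that of the main analysis, which was 0 in every setting for each siRNA. For thapsigargin, 110 of 114 were kept in this sense. The exceptions were bin counts, whose number of tested bins changed (36 with 15-nt bins, 13 with 60-nt bins, 3 before the intron alone), and the arrest window in XBP1u-frame reads, −0.25 points. In the same reads the window gave −0.51 for Hsp70L1 and 1.49 for Pelo siRNA. The cause was not tested. The XBP1u-frame window, the bins before the intron alone and a P-site shift were added after the data were seen.

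The replicate block changed the call of 2 planned results, both to past the threshold. These were the level with Hsp70L1 siRNA, −0.20 on the log2 scale in both analyses (adjusted p 0.023 with the block, 0.16 to 0.65 over the other settings), and the share past the XBP1u stop codon with Hsp70L1 siRNA, −2.57 points in both (0.047, and 0.019 to 0.54 over the other settings). It removes the offset between replicate numbers. Leaving out 1 library at a time gave −3.34 to −1.80 for that share with Hsp70L1 siRNA, passing without the first control siRNA or the second double siRNA library in DMSO. With Pelo siRNA it gave −0.27 to 1.27 past the stop codon, −1.83 to 0.59 for the arrest window and −0.40 to 0.032 for the intron. For the intron with Hsp70L1 siRNA it gave −0.050 to 0.38, negative only without its second DMSO library. Differences of the Hsp70L1 effect between treatments took either sign: −0.065 to 0.21 for the level, −1.84 to 1.23 past the stop codon (0.28 as log2 density, 0.22 as logit), −2.10 to 2.73 for the arrest window (−1.75 without its margin, −1.89 around its peak) and −0.56 to 0.30 for the intron (0.14 on the log2 scale). The added frame and pause results are not among the 411. Leaving out 1 library kept the call of the frame share in 14 of 16 cases with Hsp70L1 siRNA and in 3 of 16 with Pelo siRNA, and other settings kept it in 5 of 5 and 1 of 5. The difference between treatments also took either sign for the frame share, −5.13 to 0.47, and the pause at position 839, −3.03 to 2.59. That pause with Hsp70L1 siRNA gave −0.0056 to 2.80, and with Pelo siRNA 0.60 to 3.41. Simulated bins that changed 1.5-fold were called in 27.5% of cases.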

Other observations

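The measures and tests in this part were chosen after the data had been seen, apart from the splits of the bins. The frame and pause measures were taken from several frame and density measures that were looked at, and are adjusted over a family of 9 tests. Reading frame told the 2 proteins apart where their frames overlap, between the intron and the arrest window (positions 596 to 766). In the coding part before the intron, 66.8% of pooled DMSO reads and 68.5% of pooled thapsigargin reads lay in the common frame. In the overlap, XBP1s-frame reads as a share of XBP1s-frame and XBP1u-frame reads were 39.6% ± 5.9 in DMSO (SD, n = 8) and 70.9% ± 5.1 in thapsigargin (SD, n = 8). The rise was 31.3 percentage points, in 8 of 8 pairs (exact permutation p = 0.0015, adjusted p = 0.014). Corrected for out-of-frame reads, the overlap reads of the control siRNA cells were 26.4% ± 12.6 XBP1s-frame in DMSO and 79.2% ± 6.5 in thapsigargin (SD, n = 2 each). Read density past the XBP1u stop codon was 29.8% ± 18.1 of that before the intron in DMSO and 87.6% ± 5.1 in thapsigargin (SD, n = 2 each).

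Hsp70L1 siRNA lowered this XBP1s-frame share by 6.30 percentage points (95% interval of the difference −10.9 to −1.65), in 8 of 8 pairs. The exact permutation p was 0.0062 and the adjusted p 0.028, with 0.035 under the replicate block and 0.014 to 0.10 over all settings tried. In thapsigargin the share was 67.2% ± 3.7 with Hsp70L1 siRNA and 74.6% ± 3.0 without, and in DMSO 37.1% ± 6.1 and 42.2% ± 5.1 (SD, n = 4 each). The call was lost without the second control siRNA library in DMSO (−4.90, adjusted p = 0.083) and without the first Hsp70L1 siRNA library in DMSO (−5.16, adjusted p = 0.10). The difference of its effects between treatments was −2.33 points (exact permutation p = 0.67, under a null of no Hsp70L1 siRNA effect in any stratum). Pelo siRNA gave 5.18 points more, in 6 of 8 pairs (exact permutation p = 0.015, adjusted p = 0.046). That call was lost under the block (adjusted p = 0.094, and 0.014 to 0.15 over all settings tried), with a linear model, without the 3 highest positions and with each library corrected for its own frame (5.14, adjusted p = 0.065). Leaving out 1 library at a time kept the call in 3 of 16 recalculations, with values from 3.78 to 6.58 over all 16.

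Some technical explanations for the lower share with Hsp70L1 siRNA were tested. A looser reading frame in those libraries would move the measure toward 50% everywhere, and so raise it in DMSO, where it was lower. Before the intron the same measure differed by −0.46 points (95% interval −4.47 to 3.56). With each library corrected by its own value there, the difference in the overlap was −5.11 (exact permutation p = 0.011, adjusted p = 0.046), so a looser frame alone does not account for it. Without the 3 highest positions of the overlap the difference was −6.20 (exact permutation p = 0.0077). A candidate explanation, as a hypothesis, is that less spliced XBP1 mRNA was on ribosomes. In thapsigargin, intron reads relative to those before the intron were 0.28 points higher (exact permutation p = 0.28) and the share past the XBP1u stop codon differed by −2.72 points (exact permutation p = 0.11). The thapsigargin libraries alone allow 36 relabellings, so neither test could give a p under 0.05. The difference in the share past the stop codon was −0.95 without Pelo siRNA and −4.49 with it. Without Pelo siRNA, the corrected XBP1s-frame share of the overlap went from 79.2% to 64.0%, whereas density past the stop codon went from 87.6% to 90.0% of that before the intron. With Pelo siRNA they went from 82.6% to 74.1% and from 98.2% to 81.0%. The measures disagree without Pelo siRNA, so the explanation stays open, and splicing of the mRNA itself was not analysed here.

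The pause at position 839 was 22.9% ± 5.7 of XBP1u-frame reads past the intron in DMSO and 18.9% ± 3.6 in thapsigargin (SD, n = 8 each). This difference of −4.06 points, lower in 6 of 8 pairs, did not pass the test (exact permutation p = 0.12, adjusted p = 0.26). Over the siRNA conditions it ran from −12.1 to 3.76 points. Leaving out 1 library at a time gave −5.46 to −2.65. The difference passed only without the second Hsp70L1 siRNA library in DMSO (−5.46, adjusted p = 0.035, against up to 0.84 without another library). The XBP1u-frame reads in the denominator were not corrected for out-of-frame XBP1s reads. Past the XBP1u stop codon, 10.7% of pooled thapsigargin reads lay in the XBP1u frame. The difference therefore does not separate a weaker pause from more XBP1s reads in the denominator. The difference with Hsp70L1 siRNA was 1.40 points (exact permutation p = 0.56) and that with Pelo siRNA 2.01 points (exact permutation p = 0.48), neither past the threshold. Other high positions in thapsigargin, named after their values were seen, were 1003 at 8.17 ± 3.42 RPM and 634 at 6.28 ± 1.74 RPM, both in the XBP1s frame, and between them in height 287 in the common coding part, at 6.61 ± 2.64 RPM in the common frame (SD, n = 8 each).

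The XBP1 level was higher in replicate 2 than in replicate 1 in all 8 groups, by 1.11-fold to 1.45-fold. Replicate 2 was also the deeper library in every group, by 1.14 to 2.38 times. Since 0 of 8 groups had a second library that was not deeper, library depth and replicate number cannot be told apart here. Shared handling of same-numbered libraries may account for it as well. Replicate differences along XBP1 correlated above 0.1 in 28 of 28 pairs of groups over the filtered bins and in 24 of 28 over all coding bins. Replicate 2 differed from replicate 1 in 14 of 40 bins in edgeR's quasi-likelihood test.

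In DMSO, 454 reads lay past the XBP1u stop codon at positions 863 to 1218. If these came from ribosomes that read through that codon they would keep the XBP1u frame, but 11.2% did (Wilson 95% interval 8.65 to 14.5) and 68.1% were in the XBP1s frame, near the 69.5% of thapsigargin. The interval pools the DMSO libraries of all siRNA conditions and leaves out the spread between them. By library, the XBP1u-frame share ran from 0% to 28.1%, each time below the XBP1s-frame share of the same library. These reads are therefore consistent with translation of spliced XBP1 mRNA in cells without added stress, as a hypothesis.

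For the bins, 100 splits of the 16 libraries within strata were compared. The 23 bins called for thapsigargin were reached by 1 of 100 splits, the real one. No lower rate can come from 100 splits, so chance is unlikely but not excluded. The other splits mixed DMSO and thapsigargin libraries on each side, so the treatment effect counted partly as spread in them. The highest other split gave 14 and followed the replicate number in 8 of 16 libraries. For Hsp70L1 siRNA, where 0 bins were called, 100 of 100 splits gave as many, which tests nothing because any split calls at least 0, and the highest other gave 14. That split followed the replicate number in 16 of 16 libraries, which points to a structure of the samples, and with the replicate block Hsp70L1 siRNA still had 0 bins. For Pelo siRNA, with 0 bins, 100 of 100 splits gave as many, which again tests nothing. The highest other gave 6 and followed the replicate number in 12 of 16 libraries.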
